A study of Mus musculus with 12 samples.

How the data were processed

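Gene expression was measured by RNA sequencing in 12 mouse libraries that form 4 groups of 3. The groups are control and Phb knockdown GC2 cells (an immortalised mouse spermatocyte line), and spermatocytes from control and conditional Phb knockout mice. Per the labels' protocols, the testis tubules were digested with enzymes, germ cell populations were enriched by flow sorting after staining with a Hoechst DNA dye, and libraries were made with a directional kit, which marks strand. How the knockdown was made is not given in the sources used here. The design text calls the libraries biological replicates without naming the cultures or animals behind each one, so p-values measure the spread between these samples, which may be technical.

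The authors deposited 1 FPKM value per gene row and library, with 2 decimals. FPKM is the number of fragments scaled to transcript length and to the mapped fragments of the library. It does not correct for composition, so a gene group that takes a larger share of the RNA lowers the values of all others. Per the submitters' processing notes, HISAT2 version 2.1.0 and DESeq were used, and the builds GRCm38 and mm10 are named without a role. The quantifier, the annotation release and any filter are not given in the sources used here. The GC2 libraries share 1 set of 25911 gene rows and the spermatocyte libraries another of 36987, so each kind of sample was tested on its own and levels were not compared between them.

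Some rows name several genes, 402 in GC2 and 366 in spermatocytes, and such a value cannot be given to 1 of them. Some named rows hold assembled transcripts only, 1177 in GC2 and 225 in spermatocytes, and a gene name can stand on more than 1 row. Rows without a gene name, 1200 in GC2 and 164 in spermatocytes, were left out of the comparisons. They held 2.11% to 2.20% of the FPKM total in GC2 control libraries, 3.43% to 3.93% in GC2 knockdown, 0.901% to 0.918% in spermatocyte control and 0.750% to 0.754% in spermatocyte knockout.

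The design had provided for counts or for normalized values. The deposited values are FPKM, so the test for normalized values was used and the count tests were not run. It was limma (version 3.58.1, in R 4.3.3) with a trend of the variance with expression, on log2(FPKM + 1). A row was tested if it reached 1 FPKM in at least 3 of the 6 libraries compared, and was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. All adjusted p-values of genes come from this test. For the 8967 genes tested in both kinds of sample, the difference between both fold changes was tested in 1 limma fit of all 12 libraries. The overlap of calls was tested with a one-sided Fisher's exact test per pair of directions, which is descriptive because genes are not independent. There were 35 gene lists, fixed before the data were examined. A list with at least 5 tested rows was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Figures and summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

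The rule for named genes was also fixed before the data were examined. It takes Phb and Phb2. It takes the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 FPKM, groups that did not overlap and no clone name. It takes up to 6 called members of each list with the smallest adjusted p, and the most abundant gene of a cell type list. For the comparison of both contrasts it takes the 6 same-sign and the 6 opposite-sign genes called in both with the largest smaller change. A gene outside the rule is said to be chosen after its values were seen. Positions are from GENCODE M21 on GRCm38.

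Depth is not stated. From the steps between low values, spermatocyte control libraries held about 14.8 M to 15.7 M fragments and knockout libraries 11.1 M to 15.5 M. The same estimate rested on few rows in GC2 and is not used. Pearson's r between replicates, across genes, was 0.924 to 0.937 in GC2 and 0.984 to 0.988 in spermatocytes. Among rows with at least 500 fragments by this estimate, the variance between spermatocyte replicates was 1.81 times the estimated counting variance in controls and 1.72 times in knockouts. Small fold changes therefore pass the test in spermatocytes.

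The tests were run on simulated data with 200 changed genes. These were drawn from rows with a control mean of at least 5 FPKM on the log scale, GC2 control for the difference. The noise was independent between genes. Recovery of lower rows was not simulated, and the real data held many more calls, so the shares may not carry over to them. In GC2, with 10791 rows, 49.3% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 84.8% of those changed 4-fold were recovered, and 4.96% of calls were unchanged genes. In spermatocytes, with 15957 rows, the same shares were 73.1%, 91.0% and 97.0%, and 4.40% of calls were unchanged genes. For the difference between both contrasts, with 8967 genes, 2.63% of calls were unchanged genes when each gene had 1 spread, 15.8% when its spread differed between GC2 and spermatocytes, and 31.5% when it differed between all groups.

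The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, quantile normalization, median centring, removal of mitochondrial rows, the replicate number as a block, 1 fit of all libraries, leaving out each library in turn, and for the overlap a 2-fold threshold. Chosen after seeing the data were trimmed-mean scaling, rows of 1 gene summed, removal of assembled rows, no trend of the variance, and for the difference other estimates of the spread and a pseudocount of 0.1.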

Results

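The data are FPKM values of 12 mouse RNA-seq libraries, 3 each from control GC2 cells, Phb knockdown GC2 cells, control spermatocytes and Phb knockout spermatocytes. Phb encodes prohibitin, which forms a complex with Phb2 in the inner mitochondrial membrane. The FPKM totals were 203973 to 206711 in GC2 control libraries, 194949 to 201776 in GC2 knockdown, 289707 to 292931 in spermatocyte control and 290427 to 297362 in spermatocyte knockout. Levels are mean ± SD in FPKM over the 3 libraries of a group, control first.

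The first question is whether the targeted gene was lower in the libraries labelled as depleted. In GC2 cells Phb (ENSMUSG00000038845.11, chromosome 11, 95666957 to 95680773, plus strand, GRCm38) fell from 54.3 ± 2.15 to 20.02 ± 2.31 FPKM, a log2 fold change of -1.40 (SE 0.090, adjusted p = 0.00062). The control libraries held 56.62, 53.99 and 52.36 FPKM and the knockdown libraries 22.66, 18.37 and 19.02. In spermatocytes Phb fell from 13.3 ± 0.634 to 11.6 ± 0.241 FPKM, a log2 fold change of -0.18 (SE 0.042, adjusted p = 0.0074), with 12.6, 13.35 and 13.86 FPKM in the control and 11.81, 11.33 and 11.53 in the knockout libraries. Phb2 was at 31.5 ± 2.18 FPKM in control and 30.6 ± 0.793 in knockdown GC2 cells, with no call (adjusted p = 0.698). In spermatocytes the row shared by Phb2 and Gm23547 rose from 23.04 ± 0.976 to 26.99 ± 0.215 FPKM (log2 fold change 0.22, adjusted p = 0.0016). The spermatocyte call of Phb was lost with quantile normalization, median centring and removal of mitochondrial rows, at adjusted p = 0.17, 0.63 and 0.062. A gene-level value does not show whether an exon was deleted, so it is a weak check of the knockout label.

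**Figure D1:**
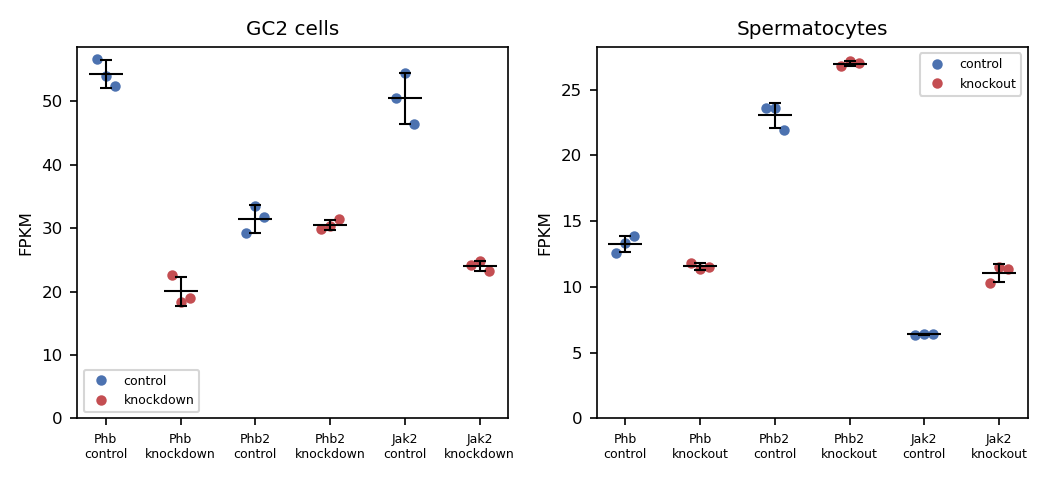
FPKM of Phb, Phb2 and Jak2 in each library of GC2 cells and spermatocytes, with points for libraries and the mean and SD of each group of 3. Phb fell from 54.3 to 20.02 FPKM in GC2 cells and from 13.3 to 11.6 in spermatocytes.

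The second comparison asks which genes differed between Phb knockdown and control GC2 cells. Interferon-stimulated genes fell together. Of 45 tested, 42 fell, each at least 2-fold, and 0 rose. Ifit1, which encodes an interferon-induced protein that binds viral RNA, fell from 80.5 ± 0.912 to 2.53 ± 0.193 FPKM. The antiviral enzyme gene Oas1a fell from 39.1 ± 2.86 to 2.05 ± 0.0208, the guanylate-binding protein gene Gbp3 from 35.98 ± 1.41 to 1.78 ± 0.157 and Bst2, whose product tethers viruses to the cell, from 167 ± 15.6 to 13.1 ± 5.95. Usp18, which restrains interferon signalling, fell from 19.5 ± 2.403 to 0.27 ± 0.0794, and Ifi44, Mx2 and Xaf1 fell as well (log2 fold changes -3.58, -3.48 and -3.11). The list median was -2.29 (adjusted p = 5.4e-29, and adjusted p = 0.0043 with an estimated correlation).

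Atf4 targets of the integrated stress response fell in 32 of 45 tested genes and rose in 0 (median -0.54, adjusted p = 6.0e-13, and adjusted p = 0.011 with an estimated correlation). Atf4 itself fell from 274 ± 6.18 to 170.04 ± 2.33 FPKM, the asparagine synthetase gene Asns from 102 ± 0.82 to 55.3 ± 0.601, Cth, which encodes an enzyme of cysteine synthesis, from 9.99 ± 0.293 to 2.13 ± 0.176 and Sesn2 from 11.7 ± 0.689 to 2.63 ± 0.168. Of the JAK and STAT genes, 6 of 22 fell and 4 rose, and the list was not called (adjusted p = 0.24). Without 1 library 5 to 7 of them fell and 1 to 3 rose, with only 1 that rose without any library but control replicate 3. The kinase gene Jak2 (chromosome 19, 29251828 to 29313080, plus strand, GRCm38) fell from 50.4 ± 4.03 to 24.05 ± 0.8398 FPKM (log2 fold change -1.04, SE 0.071, adjusted p = 0.00077). Stat2 fell from 11.5 ± 0.136 to 3.75 ± 0.236 and the oncostatin M receptor gene Osmr from 11.1 ± 0.1701 to 4.39 ± 0.1, while Pim1 rose from 21.6 ± 1.33 to 33.7 ± 0.355.

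Matrix genes fell in 20 of 34 and rose in 4, with the collagen gene Col1a2 going from 54.4 ± 2.13 to 10.8 ± 0.265 FPKM and the proteoglycan gene Bgn from 35.1 ± 1.396 to 4.71 ± 0.327. Inflammatory genes fell in 12 of 19 and rose in 1, with the acute-phase gene Saa3 going from 55.96 ± 3.76 to 1.503 ± 0.175 and the chemokine gene Ccl7 from 74.4 ± 6.22 to 5.42 ± 0.624. Cytosolic ribosomal protein genes fell in 43 of 86, with a median of -0.36 and Rpl8 going from 761 ± 46.9 to 492 ± 5.54. Nuclear genes of oxidative phosphorylation fell in 27 of 74 (median -0.22), with Cyc1, which encodes cytochrome c1, going from 95.7 ± 2.0996 to 68.4 ± 0.751. Mitochondrial ribosomal protein genes fell in 14 of 77 and rose in 1. Cholesterol synthesis and uptake genes rose in 8 of 24 and fell in 0, with Idi1 going from 9.45 ± 1.12 to 16.9 ± 0.648. These 6 lists were called at adjusted p = 2.8e-06, 6.0e-05, 8.1e-11, 9.1e-05, 0.019 and 7.5e-05 in the order given. Without 1 library, the counts of genes that fell ranged from 23 to 46 for cytosolic ribosomal proteins, from 14 to 25 for oxidative phosphorylation and from 9 to 14 for mitochondrial ribosomal proteins. They moved over 1.5 times without any library but knockdown replicate 1 for the first, without control replicates 1 and 3 and knockdown replicates 2 and 3 for the second, and without control replicate 3 and knockdown replicate 2 for the third. The mitochondrial ribosomal call was also lost without knockdown replicate 2, at adjusted p = 0.062. With an estimated correlation none of the 6 was called, at adjusted p = 0.12, 0.15, 0.16, 0.27, 0.16 and 0.12. Adjusted over the list alone, 43 interferon-stimulated, 36 Atf4 target, 7 JAK and STAT, 23 matrix, 14 inflammatory, 54 cytosolic ribosomal, 27 oxidative phosphorylation and 13 mitochondrial ribosomal genes fell and 10 cholesterol genes rose. Genes of the mitochondrial unfolded protein response fell in 2 of 19 and rose in 0 (0 fell over the list alone). Prohibitin and inner-membrane quality control genes fell in 3 of 18, Phb among them, and rose in 0. Neither list was called (adjusted p = 0.75 each). Of 13 mitochondrially encoded genes 1 was tested, with no call.

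**Figure D2:**
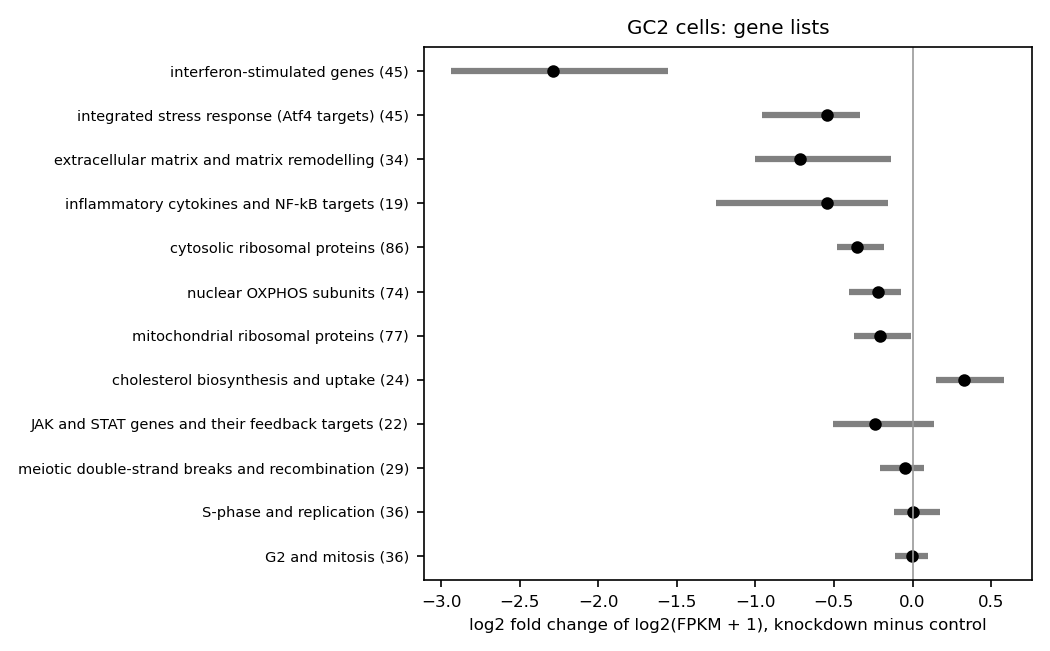
Median (point) and interquartile range (bar) of the log2 fold changes on the log2(FPKM + 1) scale, knockdown minus control, for 12 gene lists in GC2 cells, with the number of tested rows in brackets. Interferon-stimulated genes lie lowest, at a median of -2.29, and the sign of the G2 and mitosis median, close to 0, changes with the scaling.

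Among single genes, the mesothelin gene Msln rose from 38.3 ± 1.94 to 213 ± 8.85 FPKM, the tetraspanin gene Tspan8 from 5.62 ± 0.677 to 44.6 ± 1.11, the pantetheinase gene Vnn1 from 12.3 ± 3.53 to 67.5 ± 15.9 and the retinol dehydrogenase gene Rdh10 from 4.84 ± 0.0603 to 27.6 ± 1.23. The row shared by the keratin genes Krt15 and Krt19 rose from 0.723 ± 0.367 to 16.7 ± 4.98, and Serpinf1 fell from 23.04 ± 0.539 to 0.567 ± 0.145. Assembled rows of Zfp808 rose to 59.9 and 15.3 FPKM and one of Olfr1033 to 108, and an assembled row of Ankrd12 at 38.8 FPKM in control was listed at 0 in all knockdown libraries. The annotated row of Olfr1033 rose too, those of Zfp808 and Ankrd12 were not called, and another assembled row of Ankrd12 rose from 1.24 to 6.11. Pgk1-rs7, a near-identical copy of Pgk1, was at 22.05 ± 3.28 FPKM in control and listed at 0 in all knockdown libraries, which is uncertain because reads can be shared between the copies. Filip1l rose from 0.74 ± 1.17 to 12.7 ± 5.198 on its annotated row and fell from 355 ± 13.3 to 194 ± 57.4 on an assembled row, and the sum of both rows fell. Malat1 rose from 6.98 ± 0.705 to 46.7 ± 24.5 (adjusted p = 0.022). The call of Malat1 was lost without any 1 of the 3 control libraries or of knockdown replicates 2 and 3, at adjusted p = 0.061, 0.071, 0.065, 0.065 and 0.069, and that of Filip1l without knockdown replicate 2 or 3, at adjusted p = 0.053 each.

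Over 10791 tested rows, 2649 were called, 1153 higher and 1496 lower, with 140 higher and 239 lower by at least 2-fold. Calls were uneven over the chromosomes. On chromosome 18, 72 rows were higher and 14 lower, and on chromosome 4, 117 and 41. On chromosome 9, 21 rows were higher and 124 lower, and on chromosome 15, 22 and 96. The cause of this unevenness was not tested. Groups did not overlap in 44.9% of rows, where chance gives 10%. With quantile normalization, 53.6% of 2620 calls were higher, against 43.5% in the main test. Without knockdown replicate 2 or 3, the higher calls numbered 750 and 744.

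The third comparison asks which genes differed between Phb knockout and control spermatocytes. Genes of late germ cells fell furthest. All 32 tested spermatid markers fell, and Prm2, whose protamine packs sperm DNA, went from 198 ± 2.399 to 0.74 ± 0.131 FPKM. Of 28 pachytene and diplotene genes, 27 fell and 0 rose, with the testis lactate dehydrogenase gene Ldhc going from 1428 ± 10.5 to 5.41 ± 0.6304 and the chaperone gene Hspa2 from 318 ± 1.402 to 30.8 ± 0.716. In the piRNA pathway, which silences transposons in germ cells, 21 of 22 genes fell, with Piwil1 going from 136 ± 6.98 to 1.75 ± 0.09504 and Tdrd6 from 109 ± 0.554 to 0.32 ± 0.118. The medians were -4.03, -3.13 and -1.51, with adjusted p = 9.6e-11, 3.3e-10 and 5.4e-07, and adjusted p = 0.024, 0.039 and 0.028 with an estimated correlation.

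Earlier meiotic genes went both ways. Recombination genes fell in 32 of 56 and rose in 10, with the crossover factor gene Cntd1 going from 21.1 ± 0.482 to 1.68 ± 0.08505 FPKM and Spo11, whose product makes meiotic DNA breaks, from 17.4 ± 0.165 to 2.57 ± 0.2. Synaptonemal complex and cohesin genes fell in 16 of 23 and rose in 4, with Syce1 going from 172 ± 4.01 to 21.5 ± 0.728. Both lists were called, at adjusted p = 0.011 and 0.00997, and lost the call with an estimated correlation, at adjusted p = 0.11 and 0.091; the recombination call was also lost with median centring, at adjusted p = 0.052, where 21 genes fell and 15 rose. Of 16 leptotene and zygotene genes, 7 rose and 8 fell, with Prdm9, which sets sites of recombination, rising from 5.42 ± 0.217 to 7.63 ± 0.163. Of 23 spermatogonial markers, 6 rose and 10 fell, with Dmrt1 rising from 44.7 ± 0.951 to 61.6 ± 0.295 and Dmrtb1 falling from 238 ± 13.4 to 6.32 ± 0.438. Neither list was called (adjusted p = 0.98 and 0.66), and the signs of both medians changed with the scaling. With median centring 9 leptotene and zygotene genes rose and 4 fell, and 9 spermatogonial markers rose and 2 fell, and with quantile normalization these counts were 8 and 4, and 9 and 2. G2 and mitosis genes fell in 30 of 36 and rose in 3 (adjusted p = 2.8e-05, and adjusted p = 0.0395 with an estimated correlation), with the kinase gene Aurka going from 46.95 ± 1.56 to 10.2 ± 0.449.

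Markers of somatic testis cells were higher in the same knockout libraries, which came from a sort on DNA stain. Sertoli cell markers rose in 22 of 24, each at least 2-fold (median 1.83, adjusted p = 2.7e-08, and adjusted p = 0.024 with an estimated correlation). Their most abundant gene, Clu, went from 296 ± 46.8 to 1270.2 ± 92.7 FPKM, Aard from 256 ± 2.15 to 1045 ± 4.48 and the tight junction gene Cldn11 from 64.8 ± 0.598 to 306 ± 3.26. All 9 tested Leydig cell markers rose (median 1.72, adjusted p = 0.00025, and adjusted p = 0.0395 with an estimated correlation), with the steroid hydroxylase gene Cyp17a1 going from 2.69 ± 0.335 to 39.5 ± 1.42 and Hsd3b6 from 0.33 ± 0.0781 to 23.7 ± 1.58. The row shared by Jak3 and the Leydig cell hormone gene Insl3 rose from 3.103 ± 0.0603 to 82.5 ± 2.24 and cannot be given to either gene. It is counted and tested both in the Leydig list and in the JAK and STAT list below. Immune cell markers rose in 14 of 16 and peritubular myoid and endothelial markers in 13 of 14, while Aif1 and Actg2 fell from 12.1 ± 1.296 to 0.523 ± 0.179 and 11.3 ± 0.146 to 1.48 ± 0.494. The medians of these 2 lists were 0.55 and 0.49, and their calls were lost with an estimated correlation, at adjusted p = 0.17 and 0.071. The 4 tested erythrocyte rows rose, with the globin gene Hbb-bs going from 42.8 ± 2.69 to 80.5 ± 1.16.

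**Figure D3:**
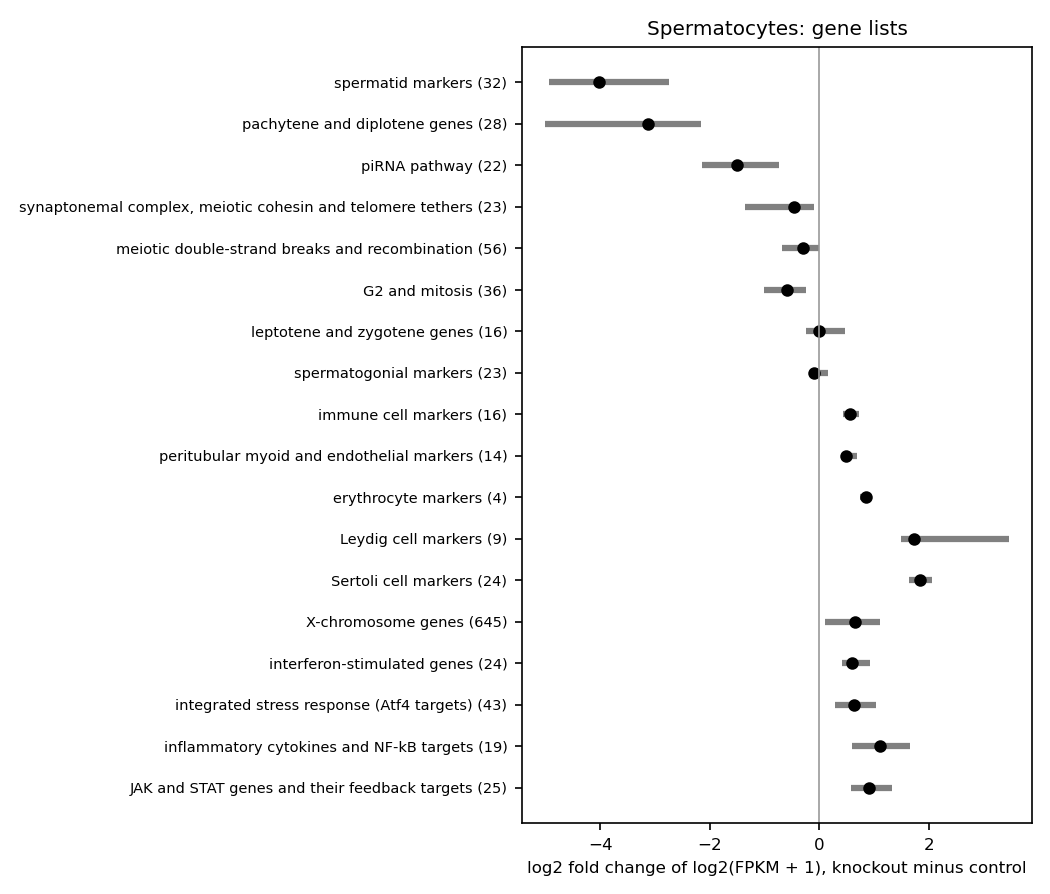
Median (point) and interquartile range (bar) of the log2 fold changes on the log2(FPKM + 1) scale, knockout minus control, for 18 gene lists in spermatocytes, with the number of tested rows in brackets. Spermatid markers lie lowest, at -4.03, and Sertoli cell markers highest, at 1.83, and the signs of the leptotene and zygotene median and of the spermatogonial median change with the scaling.

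Most genes of 4 stress and signalling lists rose in these knockout libraries, in which the Sertoli median was 1.83. Atf4 targets rose in 34 of 43 and fell in 4 (adjusted p = 2.8e-05), with the stress transcription factor gene Atf3 going from 22.1 ± 0.457 to 106 ± 2.62 FPKM and the amino acid transporter gene Slc7a5 from 47.7 ± 1.13 to 99.5 ± 0.954. Inflammatory genes rose in 16 of 19 and fell in 1 (adjusted p = 0.00018), with the lipocalin gene Lcn2 going from 1.53 ± 0.0473 to 63.5 ± 0.231 and the chemokine gene Cxcl1 from 5.99 ± 0.597 to 61.6 ± 0.459. Interferon-stimulated genes rose in 22 of 24 (adjusted p = 0.00027), with Ifi27 rising from 16.9 ± 0.407 to 58.3 ± 2.62 and Dhx58 falling from 11.9 ± 0.539 to 0.6 ± 0.0819. JAK and STAT genes rose in 21 of 25 and fell in 3 (adjusted p = 0.00012), with Jak1 going from 20.1 ± 0.171 to 50.5 ± 0.927 and the transcription factor gene Irf1 from 5.02 ± 0.194 to 17.2 ± 0.921. With an estimated correlation, Atf4 targets had adjusted p = 0.033 and the other 3 lists adjusted p = 0.039 each. The unfolded protein response was not called, with 16 of 26 genes higher and 9 lower for the endoplasmic reticulum (adjusted p = 0.15), and 8 of 19 higher and 4 lower for mitochondria (adjusted p = 0.17), although both lists were called without a filter (adjusted p = 0.029 and 0.037).

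In the same knockout libraries, with the Sertoli median at 1.83 and the pachytene and diplotene median at -3.13, X-chromosome genes rose in 439 of 645 and fell in 83 (median 0.66, adjusted p = 7.6e-09, and adjusted p = 0.0027 with an estimated correlation). The cause of this rise was not tested. Mitochondrially encoded genes rose in 8 of 10, with the complex I gene mt-Nd5 going from 1033 ± 7.49 to 1461 ± 12.8 FPKM, and mitochondrial rows held 11.9% to 13.3% of the FPKM total in control and 16.5% to 18.9% in knockout libraries. Their list was called at adjusted p = 0.0045 and lost the call with an estimated correlation (adjusted p = 0.14) and with quantile normalization, where only 1 gene rose (median 0.044, adjusted p = 0.98). That scaling gives each rank the same value in every library, so it cannot decide whether rows this abundant rose. The largest falls were those of Rbakdn, from 559.6 ± 7.84 to 1.27 ± 0.206, Ldhc, Adam5, Spata4, Adam3, Cmtm2b, Pgam2, Fbp1, Hrasls5 and Cetn1. The largest rises beside those named above were in the kallikrein genes Klk1b21, Klk1b24 and Klk1b27, whose values are uncertain because these paralogs can share reads, and in Agt, Ptgds and Apoc1. Adjusted over the list alone, the counts of the lists named for spermatocytes were the same, except that 9 spermatogonial markers fell.

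Over 15957 tested rows, 12672 were called, 6533 higher and 6139 lower, with 1857 higher and 3448 lower by at least 2-fold. Groups did not overlap in 81.8% of rows, where chance gives 10%. Splits of the libraries that mix control and knockout called up to 22 gene lists, against 24 in the real split. Each such split leaves part of the group difference between its sides, so the splits cannot show how strong a list call is. With quantile normalization, 62.0% of 13259 calls were higher, against 51.6% in the main test, and the median log2 fold change of all rows was 0.28 in place of 0.047.

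The fourth comparison asks whether the GC2 and spermatocyte changes differed. Many meiotic genes did not reach the filter in GC2 cells. Tested there were 1 of 16 leptotene and zygotene, 3 of 23 synaptonemal complex and cohesin, and 5 of 23 piRNA genes. Of pachytene and diplotene genes 8 of 28 were tested, and of recombination genes 29 of 57. The 6 opposite-sign genes named by the rule all fell in GC2 cells and rose in spermatocytes. The chemokine gene Cxcl10 fell in GC2 cells and rose in spermatocytes (log2 fold changes -2.15 and 2.60), as did Ly6e (-2.11 and 2.22), B2m, which encodes the light chain of MHC class I (-2.26 and 1.73), Ifi27 (-2.09 and 1.73), Rnf213 (-1.98 and 1.70) and Spp1 (-1.68 and 1.71). The difference was called for each of these 6 genes, with adjusted p from 2.4e-10 for Rnf213 to 2.0e-06 for Spp1. That outcome follows from choosing genes called in both with opposite signs, so it adds no evidence. Jak2, chosen in spermatocytes after its values were seen, rose there from 6.397 ± 0.0306 to 11.1 ± 0.653 FPKM (log2 fold change 0.70), and its difference was called (adjusted p = 1.1e-07). Sertoli, Leydig and immune cell markers rose in the same spermatocyte knockout libraries, with medians of 1.83, 1.72 and 0.55. Genes that rose in both were Malat1 (2.40 and 2.30), Rdh10 (2.29 and 1.20), Cpe (1.89 and 2.17), Gsta4 (1.61 and 1.87), Lfng (1.53 and 1.42) and Cgn (1.28 and 1.85). The difference was also called for Rdh10, Cgn, Cpe and Gsta4 (adjusted p = 4.2e-06, 1.9e-05, 0.0020 and 0.020), and not for Malat1 and Lfng (adjusted p = 0.93 and 0.83). The GC2 call of Lfng was lost without any 1 of the 3 control libraries or of knockdown replicates 2 and 3, with the lowest adjusted p, 0.051, without control replicate 3.

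**Figure D4:**
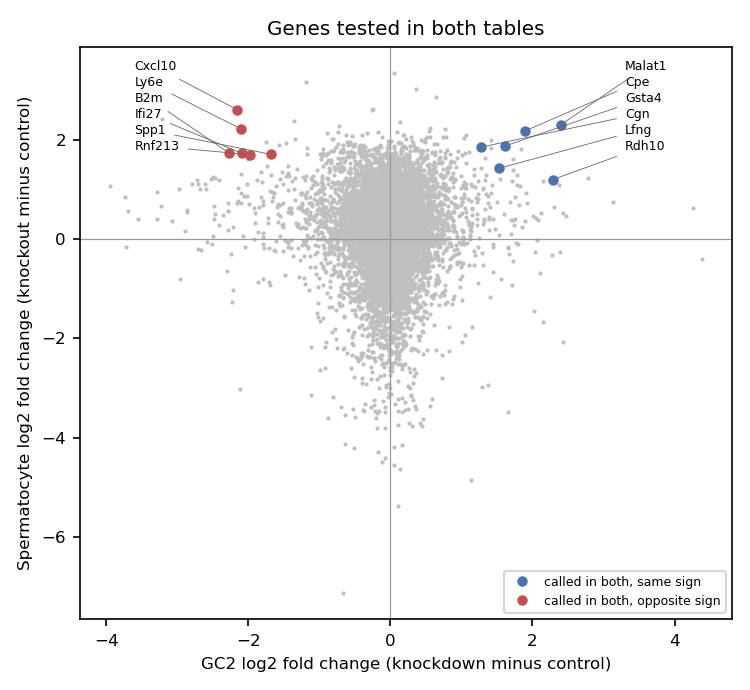
Log2 fold change in GC2 cells against that in spermatocytes, both on the log2(FPKM + 1) scale, for the 8967 genes tested in both, with each point a gene and the genes named by the rule labelled. Cxcl10 lies at -2.15 and 2.60, and Rdh10 at 2.29 and 1.20.

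Across the 8967 genes, which are not independent replicates, both fold changes had Pearson's r = -0.014 and Spearman's rho = 0.0091. A difference was called for 5481 genes, 2049 with the larger value in GC2 and 3432 with the larger value in spermatocytes. In simulated data 15.8% of such calls were unchanged genes when the spread differed between GC2 and spermatocytes, and 31.5% when it differed between all groups. Both comparisons called 493 genes higher, where 453 are expected of independent lists (Fisher's exact test, one-sided p = 0.0029). The 649 genes lower in GC2 and higher in spermatocytes compare with 594 expected (one-sided p = 0.00033 in the same exact test). Lower in both were 320 genes, with 339 expected (p = 0.91, exact), and higher in GC2 and lower in spermatocytes 226, with 258 expected (p = 0.995, exact).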

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

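The tests of chromosome-wide shifts, of a lower share of late germ cells, of Sertoli cell RNA, of loss of all germ cell stages and of Y-bearing cells were chosen after the result was seen.

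The change differed between GC2 cells and spermatocytes for 5481 of 8967 genes. Among 100 splits of the libraries within each kind of sample, the real one included, 1 called as many differences, the real one, and the highest of the others called 4342. The splits cannot exclude chance for this count, since those that mix the spermatocyte groups remove the change that most of it comes with. They also test for no change at all rather than for equal changes. In simulated data with unequal spreads, 15.8% to 31.5% of calls were unchanged genes. The 9 splits that kept the spermatocyte groups and mixed the GC2 groups called 4176 to 4342, and the 11 that kept only the GC2 groups 84 to 129, so most of the count comes with the spermatocyte change alone. Those 9 splits are too few for a share under 0.05. The GC2 log2 change less the spermatocyte change was -1.22 for Phb, -0.26 for Phb2, -1.74 for Jak2, -4.76 for Cxcl10, -4.33 for Ly6e, -3.99 for B2m, -3.82 for Ifi27, -3.68 for Rnf213 and -3.39 for Spp1. Among rows without a gene name, which no comparison used, 173 of 560 tested rows were higher and 66 lower in the GC2 knockdown. In the spermatocyte knockout 35 of 161 such rows were higher and 92 lower.

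Interferon-stimulated genes were lower in the GC2 knockdown libraries. The tables argue against 1 library as the source, since the list median was -2.29 to -2.18 without each library in turn, and against scaling, since the list median less that of all rows was -2.25 in the main test and -2.20 with quantile normalization. They also argue against chromosome-wide shifts between the cultures, since the median was -2.29 with each gene taken less the median of its chromosome, over 16 chromosomes. An effect of the knockdown and another difference between the cultures, such as their interferon exposure, stay open as untested.

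Late germ cell genes were lower and somatic markers higher in the spermatocyte knockout libraries. A lower share of late germ cells that raises all other cell types alike is argued against by the Sertoli and spermatogonial medians, which lay 1.93 apart. Loss of all stages alike is argued against by the leptotene and zygotene median, which lay 3.13 above the pachytene and diplotene median, although 12 of the 16 leptotene and zygotene genes are also on another list. More RNA of Sertoli cells may be part of the pattern, since 91.7% of Sertoli genes rose, the most abundant, Clu, from 296 ± 46.8 to 1270.2 ± 92.7 FPKM, with an interquartile span of 0.42, although the sort on DNA stain is meant to remove such cells. The first 2 tests speak only against shifts that are alike. A lower share of late germ cells with unequal shifts of the other cells stays open as untested, as does a change within the germ cells of the knockout.

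Of 6 tested Y-linked rows, 4 fell and 1 rose in the GC2 knockdown libraries (5 and 1 adjusted over the list alone), with a list call at adjusted p = 0.0058 that was lost with an estimated correlation (adjusted p = 0.15). In 4 genes chosen after their values were seen, mean FPKM went from 6.54 ± 0.602 to 0.867 ± 0.0153 for Ddx3y, from 5.52 ± 0.153 to 0.72 ± 0.108 for Eif2s3y, from 1.15 ± 0.0954 to 0.13 ± 0.0173 for Uty and from 0.827 ± 0.0115 to 0.0867 ± 0.00577 for Kdm5d, which was too low to be tested. Scaling is argued against, since the log2 fold change of Ddx3y was -1.98 to -1.94 under 4 scalings. The shares of control FPKM left, 13.3%, 13.0%, 11.3% and 10.5%, differed by 1.26 times at most, but over all tested Y rows by 13.8 times, since Erdr1 kept 66.7% and Mid1-ps1 rose from 4.26 ± 0.652 to 6.65 ± 0.898 FPKM, a call lost without any 1 library. Fewer cells with a Y chromosome in the knockdown culture and an effect of the knockdown both stay open, because the 4 genes were picked for their fall and reads of related genes in the rows of Erdr1 and Mid1-ps1 were not tested.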

How the results depend on the processing

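Trimmed-mean scaling, summed rows, removal of assembled rows, no variance trend, and other spreads and a pseudocount of 0.1 for the difference were chosen after seeing the data. The planned count-based alternatives were not run, because the values are FPKM. GC2 calls that were still tested kept their direction under each alternative except summed rows (99.6%), and spermatocyte calls except under quantile normalization (97.1%), median centring (98.8%), removal of mitochondrial rows (99.98%) and summed rows (99.9%). Without each library in turn, GC2 calls ranged from 1789 to 2258, with 744 to 962 higher and 1034 to 1296 lower, and the higher calls were 750 without knockdown replicate 2 and 744 without replicate 3. Spermatocyte calls ranged from 12223 to 12342, with 6276 to 6330 higher and 5947 to 6020 lower, and called differences from 5120 to 5523. The log2 fold change of Phb ranged from -1.49 to -1.35 in GC2 and from -0.22 to -0.15 in spermatocytes. In 1 fit of all 12 libraries, which tests 8967 genes, 6027 spermatocyte genes were called, 3768 higher and 2259 lower, where the main test called 4526 and 2580 of the same genes, and 3162 GC2 genes were called, where the main test called 898 higher and 1177 lower. The shared fit thus lowers the first count and raises the second. Without a filter, which tests more genes, 10023 differences were called. Phb in spermatocytes had log2 fold changes of -0.070 with quantile normalization, -0.024 with median centring and -0.12 with mitochondrial rows removed, with adjusted p from 0.0041 to 0.63 over its alternatives. These scalings raise the median of all rows, to 0.28, 0.21 and 0.10. With calls of at least 2-fold, which leaves fewer genes, overlaps were 30 genes higher in both (9.76 expected, Fisher's exact test, one-sided p = 4.0e-09), 8 lower in both (11.9998 expected, p = 0.92), 8 higher in GC2 and lower in spermatocytes (6.63 expected, p = 0.34), and 37 lower in GC2 and higher in spermatocytes (17.7 expected, p = 6.3e-06). The third pair moves from below to above the expected number. Filip1l in GC2 had -0.80 with rows summed, since its abundant assembled row fell. The median of mitochondrially encoded genes in spermatocytes was 0.044 with quantile normalization, below that of all rows. Quantile normalization gives each rank the same value in every library, so for such abundant rows it cannot decide whether they rose. How much of the lower median comes from this was not tested. Deviations of same-numbered libraries correlated at 0.12, 0.078 and 0.061 in GC2, where each library correlated best with its own number, so pairing by replicate number stays open there. In spermatocytes they correlated at 0.0074, -0.054 and 0.0074, and libraries did not correlate best with their own number. With the replicate block, 1985 genes were called in GC2, 12482 in spermatocytes and 5445 for the difference. Overlaps with this block were 365 genes higher in both (322 expected) and 210 lower in both (249 expected). Those higher in GC2 and lower in spermatocytes numbered 146 (183 expected), and those lower in GC2 and higher in spermatocytes 511 (438 expected). With an estimated correlation, 7 of 9 list calls in GC2 and 11 of 24 in spermatocytes were lost. Without stated depth, the counting error of values near 1 FPKM is known only roughly.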

Other observations

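The tests of other splits of the libraries were all chosen before the result was seen.

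In GC2 cells, glycolysis and hypoxia genes fell in 9 of 27 and rose in 1, with the collagen prolyl hydroxylase gene P4ha1 going from 26.1 ± 0.985 to 13.9 ± 1.06 FPKM, and the list was not called (adjusted p = 0.068), although it was without a filter and without control replicate 1 or 2 (adjusted p = 0.020, 0.024 and 0.047). Targets of Nfe2l2 went both ways, 3 higher and 6 lower of 24, with Gsta4 rising from 116 ± 10.3 to 356 ± 13.5 and G6pdx falling from 57.6 ± 2.79 to 38.4 ± 0.675. Histone and DNA modifying genes rose in 6 of 52 and fell in 3, with the methyltransferase gene Kmt2c going from 3.07 ± 0.0321 to 5.69 ± 0.225. Neither of these 2 lists was called (adjusted p = 0.86 for Nfe2l2 targets and 0.16 for histone and DNA modifying genes). Replication genes rose in 6 and fell in 2 of 36, and recombination genes rose in 1 and fell in 5 of 29, with no list call (adjusted p = 0.46 and 0.74). Without 1 library 4 to 7 glycolysis and hypoxia genes fell (4 without knockdown replicate 2) and 0 rose, and 4 to 5 targets of Nfe2l2 fell and 3 to 4 rose. In the same way 3 to 4 replication genes rose (3 without control or knockdown replicate 3) and 1 to 3 fell, 2 to 5 recombination genes fell (2 without control replicate 2 or knockdown replicate 3, and 3 without control replicate 1), and 4 to 5 histone and DNA modifying genes rose and 0 to 1 fell. The smooth muscle actin gene Acta2 fell from 93.8 ± 4.53 to 16.8 ± 0.716. Adjusted over the list alone, 2 glycolysis and hypoxia genes and 5 targets of Nfe2l2 rose, 3 recombination genes fell, and 4 histone and DNA modifying genes rose and 0 fell.

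In knockout spermatocytes, cytosolic ribosomal protein genes rose in 72 of 90 and fell in 7 (adjusted p = 6.3e-07, and adjusted p = 0.024 with an estimated correlation). Rps4x rose from 66.5 ± 1.598 to 179 ± 2.12 FPKM, while Rpl39l and Rpl10l fell from 184 ± 4.95 to 41.6 ± 1.68 and from 122 ± 1.38 to 29.8 ± 2.72. Glycolysis and hypoxia genes rose in 19 of 28 and fell in 6, with the hexokinase gene Hk2 rising from 11.5 ± 0.448 to 35.04 ± 0.373 and Hk1 falling from 28.5 ± 0.936 to 4.14 ± 0.0751, and the list call was lost with an estimated correlation (adjusted p = 0.14). Targets of p53 rose in 20 of 28, with Btg2 going from 28.9 ± 0.816 to 111 ± 2.36, and lost their call likewise (adjusted p = 0.061). The histone demethylase gene Kdm4d fell from 30.8 ± 0.794 to 0.89 ± 0.118. Sertoli cell markers, with a median of 1.83, were higher in the same libraries, and the counts of these lists adjusted over the list alone were the same.

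The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In GC2 the real split called 2649 genes and the highest of the others 18, and in spermatocytes 12672 and 0. For gene lists the real split called 9 in GC2 and the highest of the others 5, and in spermatocytes 24 and 22, so splits that mix the groups called nearly as many spermatocyte lists. Such splits keep part of the group difference, so they cannot show how strong a list call is. In each of these 4 cases 1 split, the real one, gave as many. For genes higher in both comparisons, 1 of 100 splits gave as many, with 493 in the real split and 8 in the highest of the others, and for genes lower in GC2 and higher in spermatocytes it was again 1, with 649 and 8. These 2 overlaps stay untested by the splits, because a split that mixes the groups calls too few genes, at most 18 in GC2 and 0 in spermatocytes, to overlap as much.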
